A study of Mus musculus with 24 samples.

How the data were processed

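The samples were 24 total RNA preparations from 12 primary B-cell lymphomas of Eμ-Myc transgenic mice, each lymphoma profiled untreated and after 5 days in culture with 0.05 µg/ml Adriamycin (ADR, doxorubicin, a DNA-damaging cytostatic drug). Per the labels, the lymphoma cells carried a retroviral Bcl2 gene, which protects cells from apoptosis, and grew on gamma-irradiated NIH 3T3 fibroblasts as a feeder layer. Biotin-labelled RNA was hybridised to Affymetrix arrays.

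The deposited table gave 1 value per probe set and array on a log2 scale. The submitters' processing notes name RMA, a background correction, normalization and summary method for such arrays, and Partek, an analysis program. Versions and settings were not given in the sources used here. The log2 scale was read from the deposited values: the lowest value of an array lay between 1.97 and 2.14 and the highest between 14.06 and 14.36, and array medians lay between 4.38 and 4.47. The scanner files were not used here, so background correction and normalization stayed as the authors made them. RMA values of weak probe sets are compressed toward a floor, which makes changes of weakly expressed genes look smaller than they are. For arrays, the number of lymphomas limits the precision.

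The table held 45101 probe sets. In the annotation used, 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were control probe sets. Of the probe sets with 1 symbol, 34741 matched a RefSeq gene by Entrez ID and 0 symbols needed an update. Each of 18193 genes was represented by the single-gene probe set with the highest mean over the 24 arrays; 9010 genes had more than 1 such probe set. No gene was named from a probe set with several symbols, and no genome coordinates were used.

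Groups were taken from the sample titles, and lymphoma numbers in the titles paired the arrays, as matched pairs are stated in the series' design text. The pairing was checked with the correlation, over the single-gene probe sets, between the untreated and the ADR array in their deviation from the group mean. That correlation lay between 0.257 and 0.589 within pairs, above 0.1 in all 12, and was higher than with any other lymphoma in 10 of 12. Correlations between arrays lay between 0.908 and 0.992, and 0 arrays were identical. Each pair came from a separate lymphoma, so p-values of single genes measure the spread between lymphomas.

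The comparison of ADR with untreated used limma 3.58.1 in R 4.3.3 with the lymphoma as a block and moderated variances (lmFit and eBayes). P-values were adjusted by the Benjamini-Hochberg method over the 18193 genes, and a gene was called changed at an adjusted p under 0.05. For 32 gene lists, camera with a preset correlation of 0.01 between genes compared each list with all other genes, adjusted over the lists. Its p-values treat the genes of a list as nearly independent and so do not measure the spread between lymphomas. The lists held 791 members, of which 728 had a single-gene probe set. Each list was also tested with camera and an estimated correlation, with fry, and with an exact two-sided sign-flip permutation test of the mean change over 12 pairs. That test has 4096 sign patterns and cannot give a p below 0.000488. Correlations across lymphomas used two-sided permutation tests with 100000 resamples, or all orderings in subsets under 10, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3; figures used matplotlib 3.10.9. They formed a family of 10 relations. Array file names in the sample descriptions of treated arrays used either "sen" (5 lymphomas) or "DOX" (7 lymphomas), which was treated as a possible processing batch.

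The lists, tests, alternatives and naming rule were fixed before the data were examined. Genes named are the 10 largest rises and 10 largest falls among called genes that changed the same way in all 12 lymphomas. In each list they are the 3 called members with the largest change in the direction of most called members and the called member with the largest change the other way, or the 2 largest changes where none was called. They also include Myc, Bcl2, Cdkn1a, Cdkn2a, Cdkn2b, Mki67, Lmnb1, Glb1, Il6 and Hk2, set as anchors. Trp53 and Suv39h1 were also set but had no single-gene probe set in the annotation used. Any other gene named was chosen after its values were seen.

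The fit was tested on simulated data with the 18193 genes and 200 known changes of ADR against untreated. It recovered 62.7% of changes of 0.5 on the log2 scale, 92.5% of changes of 1 and 98.5% of changes of 2, with 5.6% of calls false. A list shifted by 0.5 was called and 0 unchanged lists were. The simulated genes varied independently, so false list calls from correlated genes were not tested. In the data the estimated correlation within the mitosis list was 0.83. Of 200 genes with a known difference between the naming sets 130 were recovered, with 2 false calls. Alternatives covered the pairing, centring of arrays on their medians, quantile normalization, a filter on dim probe sets (log2 above 6 in at least 6 arrays), and other probe sets per gene. They also covered array weights, another variance model, the Wilcoxon signed-rank test, limma treat, a stricter threshold, each naming set alone, each lymphoma left out, and mean macrophage and fibroblast marker levels as covariates. Chosen after seeing the data were the fibroblast marker mean alone as a covariate and leaving out lymphomas 1570 and 6054, or 5560 and 403. The limit of the Cdkn2a relations to lymphomas with an untreated level below 5 was also chosen then.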

Results

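Gene expression was measured on arrays in 12 mouse B-cell lymphomas driven by Myc and protected by retroviral Bcl2, each untreated and after 5 days of ADR. There were 12 arrays per group and 12 matched pairs, and 18193 genes were tested. Per the series' design text, these lymphoma cells enter senescence, a lasting arrest of the cell cycle, on DNA damage. The comparison asks which transcripts differ between treated and untreated cells of the same lymphoma. Values are log2 expression, and changes are ADR minus untreated. For genes at or below the highest array median (4.47) in either group, which lie near the floor, levels or log2 changes are given without a fold.

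Genes of cell division fell in every lymphoma after ADR. The 10 largest falls among genes lower in all 12 pairs were Kif11, Ccnb2, Esco2, Aspm, Aurkb, Spag5, Mki67, Nuf2, Cenpf and Cenpp. Kif11, a spindle motor protein, went from 8.88 ± 0.32 to 6.15 ± 1.17 (SD, n = 12), which is 6.66-fold lower (log2 change -2.74, SE 0.30, adjusted p = 3.4e-05). Ccnb2, a mitotic cyclin, was 5.63-fold lower and Aurkb, a mitotic kinase, 5.38-fold lower. Mki67, the gene of the proliferation marker Ki-67, was 5.09-fold lower (10.77 ± 0.40 to 8.42 ± 0.83, adjusted p = 2.2e-05). The other 6 were between 4.82-fold and 5.56-fold lower.

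The largest rises among genes higher in all 12 pairs were those of Cald1, Cxcl5, Emp1, Grb10, Kitl, Col1a2, Prss23, Hmga2, Vasn and Clec4d. Cald1, an actin-binding protein of contractile cells, went from 4.27 ± 0.83 to 8.36 ± 1.96 (SD, n = 12, log2 change 4.09, SE 0.55, adjusted p = 0.000143). Of its probe sets, 3 were called higher and 1 lower. Cxcl5, a neutrophil-attracting chemokine, went from 3.58 to 7.46, and Col1a2, a chain of type I collagen, was 9.28-fold higher (adjusted p = 0.000456). Clec4d, a C-type lectin of myeloid cells, went from 7.06 ± 1.99 to 10.05 ± 2.06 (adjusted p = 1.32e-05). Cald1 and Col1a2 belong to the fibroblast marker list. The fibroblast marker mean of each array was also used as a covariate, a setting chosen after seeing the data. In that fit Clec4d (log2 change 3.23, against 2.99 without the covariate), Grb10 (0.89 against 3.25) and Hmga2 (0.82 against 3.14) stayed called. The other 7 did not: Cald1 1.20 (adjusted p = 0.0658), Emp1 1.15, Prss23 0.51, Col1a2 0.42, Vasn 0.29, Cxcl5 0.27 and Kitl 0.18. The 10 largest falls all stayed called, while among all named genes 68 lost their call in that fit and 20 turned direction, none of the 20 with a call.

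In all, 4829 genes changed by limma's paired test, 2500 higher and 2329 lower with ADR. Of these, 1012 changed at least 2-fold, 656 higher and 356 lower, and 1306 went the same way in all 12 lymphomas, 547 higher and 759 lower. A gene with no change has a 0.0488% chance of going the same way in 12 pairs. The median change of all genes was -0.01. Among 2924 called genes with several probe sets, 25 had a probe set called the other way. Markers of fibroblasts and macrophages rose with ADR. With the fibroblast marker mean as a covariate, 1071 genes were called, 446 higher and 625 lower. With the macrophage marker mean added, limma called 0 genes, with 2101 at an unadjusted p under 0.05. The fit without the lymphoma block called 3210 genes.

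The genes set in advance covered known features of arrest and of this model. Cdkn1a, which encodes the cell-cycle inhibitor p21, rose 2.21-fold (10.43 ± 0.92 to 11.57 ± 0.40, adjusted p = 0.00192) and was higher in 11 of 12 lymphomas. Lmnb1, a nuclear lamina gene, was 2.99-fold lower in 12 of 12 (adjusted p = 0.000311). Glb1, the lysosomal beta-galactosidase, rose 1.38-fold in 12 of 12 (adjusted p = 0.00474). Il6, a cytokine, rose 2.84-fold in 10 of 12 (adjusted p = 0.00366). None of these 4 calls held with the fibroblast covariate, where Cdkn1a had a log2 change of 1.08 (adjusted p = 0.152), Lmnb1 of -0.68, Glb1 of 0.29 and Il6 of 0.35. With macrophage markers added the values were 0.053, -0.22, -0.21 and -0.24. Cdkn2a, encoding p16 and p19ARF, went from 3.90 to 3.99, near the floor, a log2 change of 0.08 (SE 0.08, adjusted p = 0.527). Values of Cdkn2b (3.96 to 4.30, also near the floor) and Hk2 also did not pass, with log2 changes of 0.33 (adjusted p = 0.198) and 0.05 (adjusted p = 0.831).

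Myc, the driver, and 1 of 5 Bcl2 probe sets were called lower; whether a probe set reads the retroviral or the endogenous Bcl2 transcript was not tested. Myc was 1.68-fold lower (11.09 ± 0.47 to 10.35 ± 0.88, adjusted p = 0.0231), lower in 9 of 12 lymphomas. The Bcl2 probe set with the highest mean was 1.82-fold lower (11.85 ± 0.49 to 10.98 ± 0.83, adjusted p = 0.00402), lower in 12 of 12. The Bcl2 probe set with the largest variance within groups had a change of 0.09 (adjusted p = 0.794). With the fibroblast marker mean as a covariate the Myc estimate was 0.31 (adjusted p = 0.49) and the Bcl2 estimate -0.48 (adjusted p = 0.465).

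**Figure D1:**
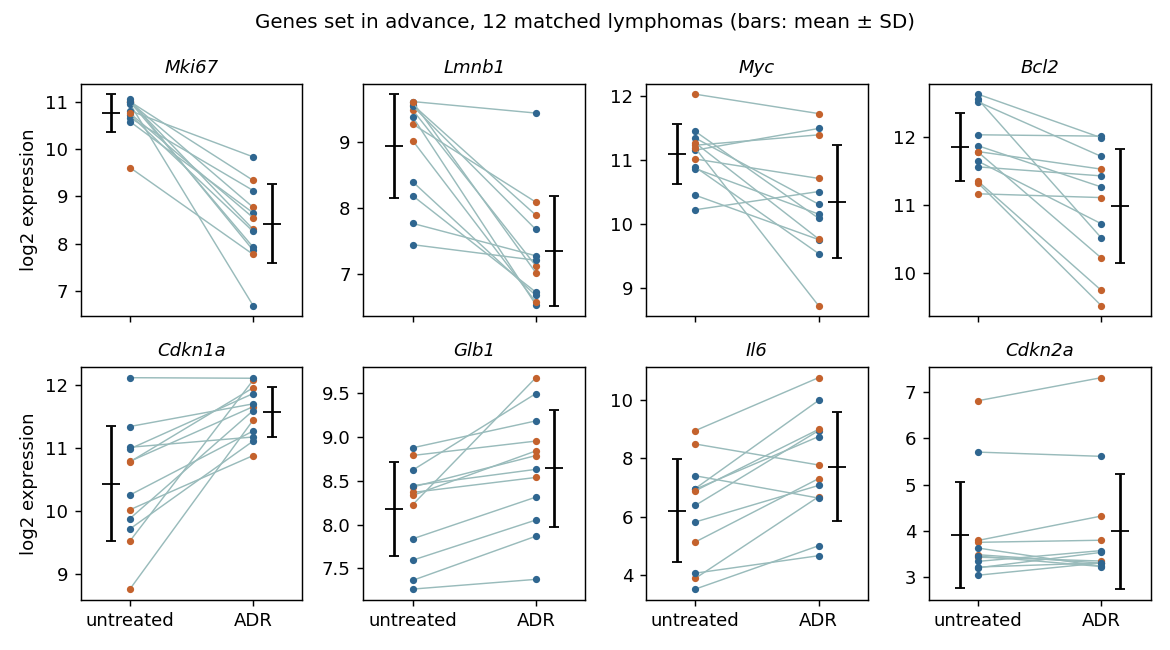
Log2 expression (vertical axes) of 8 genes set in advance in untreated and ADR arrays; lines join the 2 arrays of a lymphoma, black bars are the mean ± SD of 12, orange points are lymphomas with sen and blue with DOX in the treated array's name. Mki67 and Lmnb1 fell in all 12 lymphomas, Cdkn1a rose in 11, and Cdkn2a stayed below 5 in 10 untreated arrays.

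The mitosis list fell as a whole: 35 of 35 measured members were lower, 34 of them at least 2-fold, with a median change of -2.04 (camera adjusted p = 9.6e-31). Per lymphoma the mean change ranged from -3.74 to -0.91 and was below 0 in 12 of 12 (exact sign-flip permutation adjusted p = 0.00174). Adjusted over the list alone, 35 fell. The list had adjusted p = 0.124 with an estimated correlation. S phase and DNA replication genes fell in 32 of 33 cases, 33 adjusted over the list alone, with a median change of -1.42. Pola1, a DNA polymerase subunit, was 4.01-fold lower, the nucleotide hydrolase gene Dut 3.90-fold lower and the thymidine kinase gene Tk1 3.56-fold lower. By camera the adjusted p was 1.03e-27, and adjusted p = 0.117 with an estimated correlation. With the fibroblast marker mean as a covariate the mean changes were -2.35 for mitosis and -1.24 for S phase. All 35 mitosis genes were still called lower in that fit, and 24 S phase genes.

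DNA repair and chromatin genes also fell. In the DNA repair and checkpoint list 22 of 26 members were lower (23 adjusted over the list alone), led by Fancd2 (3.80-fold), Rad51ap1 (3.55-fold) and Brca1 (3.53-fold), which act in repair by homologous recombination or of crosslinks. The list had a camera adjusted p of 1.52e-16, and adjusted p = 0.117 with an estimated correlation. In the heterochromatin and DNA methylation list 13 of 17 fell, also 13 adjusted over the list alone. Hmgb2, a chromatin protein, was 4.16-fold lower, and Ezh2, the histone H3 lysine methyltransferase of Polycomb, 2.68-fold lower. Its camera adjusted p was 1.9e-10, and adjusted p = 0.117 with an estimated correlation. Both lists were lower in 12 of 12 lymphomas. With macrophage and fibroblast markers as covariates their mean changes went from -0.98 to -0.62 and from -0.81 to -0.37. In the fit with fibroblast markers alone 13 repair and 6 heterochromatin members were called.

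Several metabolic lists were lower. Cholesterol synthesis genes fell in 14 of 19 cases (16 adjusted over the list alone), with Idi1 3.06-fold, Stard4 2.95-fold and Fdps 2.88-fold lower. The mean change per lymphoma ranged from -1.57 to 0.00, camera gave an adjusted p of 2.24e-09, and adjusted p = 0.25 with an estimated correlation. In the TCA cycle and oxidative phosphorylation list 24 of 35 fell by small amounts (25 adjusted over the list alone, median -0.26). Fh1, the fumarase gene, was 1.79-fold lower, Idh2 1.62-fold and Idh3a 1.55-fold. Its camera adjusted p was 2.8e-10, and adjusted p = 0.124 with an estimated correlation. Nucleotide and one-carbon synthesis genes fell in 11 of 20 cases, also 11 adjusted over the list alone. Shmt1 was 2.22-fold and Shmt2 1.91-fold lower, and the ribose-phosphate kinase gene Prps1 had an adjusted p of 8.4e-05. For the list, camera gave an adjusted p of 1.26e-06, and adjusted p = 0.259 with an estimated correlation. Nucleotide synthesis was no longer called with the fibroblast marker mean as a covariate (mean change -0.04, camera adjusted p = 0.565), and the other 2 lists with macrophage markers added (-0.20 and -0.06).

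Ribosome biogenesis and MYC target genes fell in 8 of 34 cases, also 8 adjusted over the list alone. Among them were Nop58 (1.81-fold), Gar1 (1.63-fold) and Wdr12 (1.54-fold, 1 of 3 probe sets called), which act in making ribosomal RNA. Tested with camera, the list had an adjusted p of 7.3e-05, and adjusted p = 0.492 with an estimated correlation. Fry (adjusted p = 0.0806) and the sign-flip test (0.0853) did not call it. The direction turned with the fibroblast marker mean as a covariate (mean change 0.39, camera adjusted p = 1.49e-06). Proteasome genes fell in 10 of 30 cases (12 fell and 1 rose adjusted over the list alone), with Psmc6, Psma4 and Psma1 between 1.23-fold and 1.27-fold lower. Its camera adjusted p was 0.00426, and adjusted p = 0.394 with an estimated correlation. With the fibroblast covariate the mean change was 0.0033. In the glycolysis list 6 of 20 fell and 2 rose (6 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.095). Aldoc was 2.51-fold, Pdk1 1.85-fold and the lactate transporter gene Slc16a1 1.62-fold lower, while Eno2 rose from 4.38 to 5.49. With the fibroblast covariate the list was called lower (mean change -0.47, camera adjusted p = 9.2e-06).

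Fibroblast markers, listed because of the feeder layer, rose in 25 of 29 cases, 23 of them at least 2-fold and 28 adjusted over the list alone. Fn1, fibronectin, rose 11.07-fold (6.73 ± 1.09 to 10.20 ± 1.86, SD, n = 12, adjusted p = 0.000853). Lox, which crosslinks collagen, rose 10.53-fold. The mean change was 2.06 and ranged between lymphomas from -0.09 in lymphoma 1467 to 4.22 in 5560 and 4.45 in 403. By camera the adjusted p was 8.4e-14, and adjusted p = 0.25 with an estimated correlation.

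Macrophage markers rose in 16 of 24 cases (17 adjusted over the list alone) and in 12 of 12 lymphomas, with mean changes from 0.43 to 2.32. Adgre1, a surface receptor gene of macrophages, rose 4.56-fold, the Fc receptor gene Fcgr1 4.12-fold and the endotoxin co-receptor gene Cd14 3.79-fold. Many were expressed before treatment: 12 of 24 lay above 6 in untreated arrays, against 3 of 29 fibroblast markers. Lyz1, the macrophage marker with the highest level, went from 11.99 to 13.46. The list had a camera adjusted p of 2.1e-08, and adjusted p = 0.117 with an estimated correlation. Neutrophil markers rose in 3 of 13 cases, also 3 adjusted over the list alone: Lcn2 6.80-fold, Mmp8 5.50-fold and S100a8 4.58-fold. That list did not pass by camera (adjusted p = 0.0548), but it was higher in 12 of 12 lymphomas (exact sign-flip permutation adjusted p = 0.00174), was called by fry (adjusted p = 0.00114) and, without lymphomas 1570 and 6054, by camera (0.031). Markers of T and NK cells (1 of 17 rose, Gzma, and 1 fell, Klrd1), erythroid cells (0 of 7) and dendritic cells (1 of 9 fell, Flt3) did not pass as lists (camera adjusted p = 0.703, 0.856 and 0.864), and counts adjusted over each list alone were the same. Hba-a1 (3.24 to 3.41) and Slc4a1 (3.51 to 3.41), the erythroid genes with the largest differences, lay near the floor. They had log2 changes of 0.16 and -0.10 (adjusted p = 0.139 and 0.436).

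Genes of the secretory phenotype, the cytokines, proteases and growth factors released by senescent cells, rose in 26 of 36 cases and fell in 0 (27 adjusted over the list alone, median 1.02). Ereg, a growth factor, rose from 3.29 to 6.26, the protease inhibitor gene Timp2 7.26-fold and the chemokine gene Cxcl2 6.71-fold (5.30 ± 1.22 to 8.04 ± 1.45, adjusted p = 2.6e-05, higher in 12 of 12). For the list, camera gave an adjusted p of 8.5e-12, and adjusted p = 0.124 with an estimated correlation. The mean change was 1.29, against 2.06 for fibroblast markers in the same arrays. With the fibroblast marker mean as a covariate it was 0.25 (camera adjusted p = 0.314), and 1 member, Cxcl2, was called. The log2 change of Cxcl2 was 1.44 or more in every setting, though its call was lost with macrophage markers added.

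Across the 12 lymphomas, the secretory phenotype change followed the fibroblast marker change (Pearson r = 0.947, Spearman rho = 0.965, permutation p = 1e-05 for both, the smallest that 100000 resamples can give, adjusted p = 0.0001). Without lymphomas 403 and 1467, the farthest from the median of the fibroblast marker change, r was 0.927 (permutation p = 0.00015). Within the 7 lymphomas of the DOX naming set r was 0.930 (exact permutation p = 0.00397). The sen set, with 5 lymphomas, was too small. Against the macrophage marker change r was 0.206 (rho 0.112, adjusted p = 0.678), and 0.776 within the DOX set (exact permutation p = 0.0446).

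**Figure D2:**
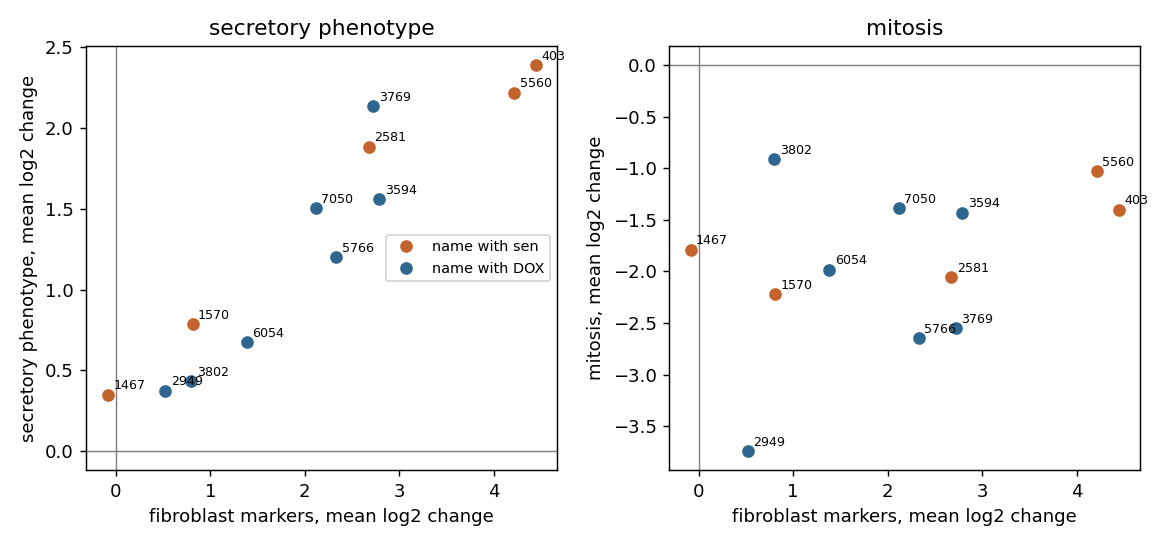
Mean log2 change of the secretory phenotype list (left) and of the mitosis list (right) against that of fibroblast markers, all as ADR minus untreated, with 1 point per lymphoma and its number. The secretory phenotype change runs from 0.35 in lymphoma 1467 to 2.39 in 403 along with the fibroblast markers (r = 0.947), while the mitosis change is below 0 at every point (r = 0.361).

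The mitosis change was not detectably related to the changes of p53 targets (r = 0.451, rho 0.175), secretory phenotype (0.295, 0.224), NF-kB targets (0.164, 0.028), lysosome (0.194, -0.042), macrophage markers (0.023, -0.112) or fibroblast markers (0.361, 0.238). Their permutation p-values for r ranged from 0.142 to 0.942, adjusted from 0.604 to 0.942. Without the 2 lymphomas farthest from the median, r of these 6 lay between -0.17 and 0.40, and within the DOX set between 0.11 and 0.63. Untreated Cdkn2a was below 5 in 10 lymphomas and at 5.70 and 6.82 in the other 2, so, after these values were seen, no r was computed over all 12. The 10 values lay between 3.04 and 3.79, near the floor, so an r over them carries little weight. Within the 10, r of untreated Cdkn2a was 0.460 with the p53 target change (rho 0.430, permutation p = 0.181) and 0.192 with the mitosis change (rho 0.091, p = 0.599), with adjusted p = 0.604 and 0.678. Without 1570 and 3769 these r were 0.566 and 0.175, and within 6 DOX lymphomas -0.08 and 0.246.

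Lysosome genes rose in 32 of 35 cases, the same adjusted over the list alone, and in 12 of 12 lymphomas. The cathepsin genes Ctsl and Ctsd rose 3.96-fold and 3.68-fold, and Atp6v0a1, a subunit of the proton pump that acidifies lysosomes, 2.60-fold (6.18 ± 0.31 to 7.56 ± 0.42, adjusted p = 9.2e-06). Its camera adjusted p was 2.9e-19, and adjusted p = 0.124 with an estimated correlation. Autophagy genes rose in 15 of 35 cases and fell in 2 (16 and 3 adjusted over the list alone). The cargo receptor gene Sqstm1 rose 2.38-fold, Map1lc3a 2.37-fold and Gabarap 1.95-fold, while Uvrag was 1.20-fold lower. Tested with camera, the list had an adjusted p of 0.000112, and adjusted p = 0.117 with an estimated correlation. Beside the fibroblast and macrophage marker rises in these arrays, the lysosome mean change was 0.82, 0.49 with the fibroblast covariate (8 members called) and 0.01 with both marker covariates. Autophagy was not called with the fibroblast covariate (0.11, camera adjusted p = 0.105).

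Interferon response genes rose in 24 of 34 cases (28 adjusted over the list alone) and in 10 of 12 lymphomas, with lymphomas 403 and 2949 at -0.41 and -0.24. Rtp4 rose 4.23-fold, Oasl2 4.11-fold and Ifit1 from 3.85 to 5.90. By camera the adjusted p was 2.03e-10, and adjusted p = 0.267 with an estimated correlation. Targets of p53, the transcription factor activated by DNA damage, rose in 13 of 27 cases, also 13 adjusted over the list alone. Phlda3 rose 3.18-fold, Plk2 2.59-fold and Eda2r from 3.85 to 5.21. The list was higher in 10 of 12 lymphomas, with 2949 at -0.40 and 6054 at -0.05. The list had a camera adjusted p of 1.55e-05, and adjusted p = 0.311 with an estimated correlation. Both lists kept their camera calls with the fibroblast covariate (0.86 with 2 members called, and 0.44 with 3) and not with macrophage markers added (-0.11 and -0.06). Over the 12 lymphomas, the 95% interval of the fitted change where fibroblast markers do not change was 0.05 to 1.66 for interferon response and -0.15 to 1.03, which holds 0, for p53 targets.

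NF-kB target genes rose in 7 of 24 cases and fell in 1, the same adjusted over the list alone. Tnfaip2 rose 3.44-fold, Traf1 1.90-fold and Cd83 1.77-fold, while the homing receptor gene Ccr7 was 1.91-fold lower. For the list, camera gave an adjusted p of 0.0218, and adjusted p = 0.491 with an estimated correlation. Fry (adjusted p = 0.0707) and the sign-flip test (0.0534) did not call the NF-kB list, nor did camera without lymphoma 2581 or in the sen set alone (0.0767). Immune ligand genes rose in 4 of 14 cases, also 4 adjusted over the list alone, among them Cd274, which encodes PD-L1 (2.50-fold, higher in 11 of 12), Nectin2 (1.97-fold) and Pvr (1.83-fold). Its camera adjusted p was 0.0364, and adjusted p = 0.387 with an estimated correlation. The call was also lost in the sen set (0.0738), without 5560 and 403 (0.0612), without the lymphoma block, and without 3594, 3769 or 7050. Neither list was called with the fibroblast covariate (mean changes -0.06 and -0.01). With macrophage markers added camera called both in the other direction (-0.61, adjusted p = 0.00024, and -0.42, adjusted p = 0.0129), with 0 members of either called. Unfolded protein response genes rose in 7 of 27 cases, also 7 adjusted over the list alone, with Atf3 1.98-fold, Ddit3 1.94-fold and Ern1 1.78-fold higher. Of their probe sets, 1 of 1 was called higher for Atf3, 1 of 2 for Ddit3 and 1 of 5 for Ern1, and 0 lower. The list had a camera adjusted p of 0.00488, and adjusted p = 0.443 with an estimated correlation. In the sen set alone camera did not call it (adjusted p = 0.0608). The mean change was 0.28, against 0.22 with the fibroblast covariate (adjusted p = 0.0837) and 0.32 with macrophage markers added (adjusted p = 0.0353).

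B cell identity genes fell in 8 of 24 cases and rose in 1 (11 and 1 adjusted over the list alone). Vpreb3 was 4.50-fold, Fcrla 2.78-fold and Cd22 2.51-fold lower, while the kinase gene Syk rose 1.83-fold. The Syk probe set with the largest variance had a change of -0.20 (adjusted p = 0.518). The list mean ranged from -1.62 in lymphoma 5560, where fibroblast markers changed by 4.22, to 0.64 in 1570. By camera the adjusted p was 0.00896, and adjusted p = 0.491 with an estimated correlation, and fry did not call it (0.0599). Camera called the list in the DOX set alone (adjusted p = 0.000444) and not in the sen set alone (0.217). The estimate turned to 0.31 with the fibroblast covariate (camera adjusted p = 0.0502), and without lymphomas 5560 and 403 it was -0.28 (adjusted p = 0.068).

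The remaining lists did not pass by camera, while fry and the exact sign-flip permutation test called the BCL2 family (adjusted p = 0.0144 and 0.0148), haematopoietic stem cell (0.0204 and 0.00481) and Wnt target (0.024 and 0.0067) lists higher, and the sign-flip test the plasma cell list (0.0258). B cell progenitor genes fell in 3 of 13 cases and rose in 1 (4 and 1 adjusted over the list alone): Myb was 3.26-fold, Bach2 3.01-fold and Igll1 1.94-fold lower, and Il7r rose 2.01-fold (camera adjusted p = 0.395). The B cell progenitor mean was -0.36, and 0.36 with the fibroblast covariate (adjusted p = 0.0854). Plasma cell genes rose in 4 of 13 cases, also 4 adjusted over the list alone, with Sdc1 2.04-fold, Xbp1 1.48-fold and Edem1 1.43-fold higher (camera adjusted p = 0.141). In MHC class I presentation 5 of 15 rose and 2 fell (6 and 2 adjusted over the list alone). H2-D1 rose 1.51-fold, Calr 1.43-fold and Tapbp 1.34-fold, and Psmb9 was 1.36-fold lower (camera adjusted p = 0.256). Of their probe sets, 4 of 9 were called higher for H2-D1, 3 of 3 for Calr and 1 of 2 for Tapbp. In MHC class II presentation 3 of 12 fell and 1 rose, the same adjusted over the list alone. H2-Ob was 2.28-fold, H2-Oa 1.76-fold and Ifi30 1.27-fold lower, and Ctss rose 1.72-fold (camera adjusted p = 0.392). Class I was called higher with the fibroblast covariate (mean change 0.23, adjusted p = 0.047), and class II lower with macrophage markers added (-0.79, adjusted p = 0.000438).

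In the BCL2 family 4 of 14 members rose and 1, Bcl2, fell, the same adjusted over the list alone. The anti-apoptotic genes Bcl2l1, Bcl2l2 and Mcl1 rose 1.93-fold, 1.41-fold and 1.34-fold (list camera adjusted p = 0.141). Of their probe sets, 2 of 4, 1 of 4 and 6 of 6 were called higher and 0 lower. With the fibroblast covariate these genes had changes of 0.15, -0.15 and 0.36 and none was called, and Mcl1 was -0.12 with macrophage markers added. Haematopoietic stem cell genes rose in 5 of 18 cases, also 5 adjusted over the list alone. They were led by Cd34 (3.19 to 5.74), Procr (4.59-fold) and Mecom (3.55 to 4.47, 1 of 3 probe sets called). That list had a camera adjusted p of 0.216. With the fibroblast covariate the list mean went from 0.34 to -0.039 and Cd34, Procr and Mecom to -0.17, 0.17 and -0.49, none of the 3 called. Wnt target genes rose in 4 of 19 cases and fell in 1, the same adjusted over the list alone. Jun rose 2.03-fold, Ccnd1 1.64-fold and Sox9 from 4.42 to 5.64, and Lgr5 fell from 5.32 to 4.40 (camera adjusted p = 0.514). None of the 4 was called with the fibroblast covariate, where Sox9 (-0.21) and Lgr5 (0.34) turned, and Jun turned with macrophage markers added (-0.41). The median of the Wnt list was -0.01 and its mean 0.11.

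**Figure D3:**
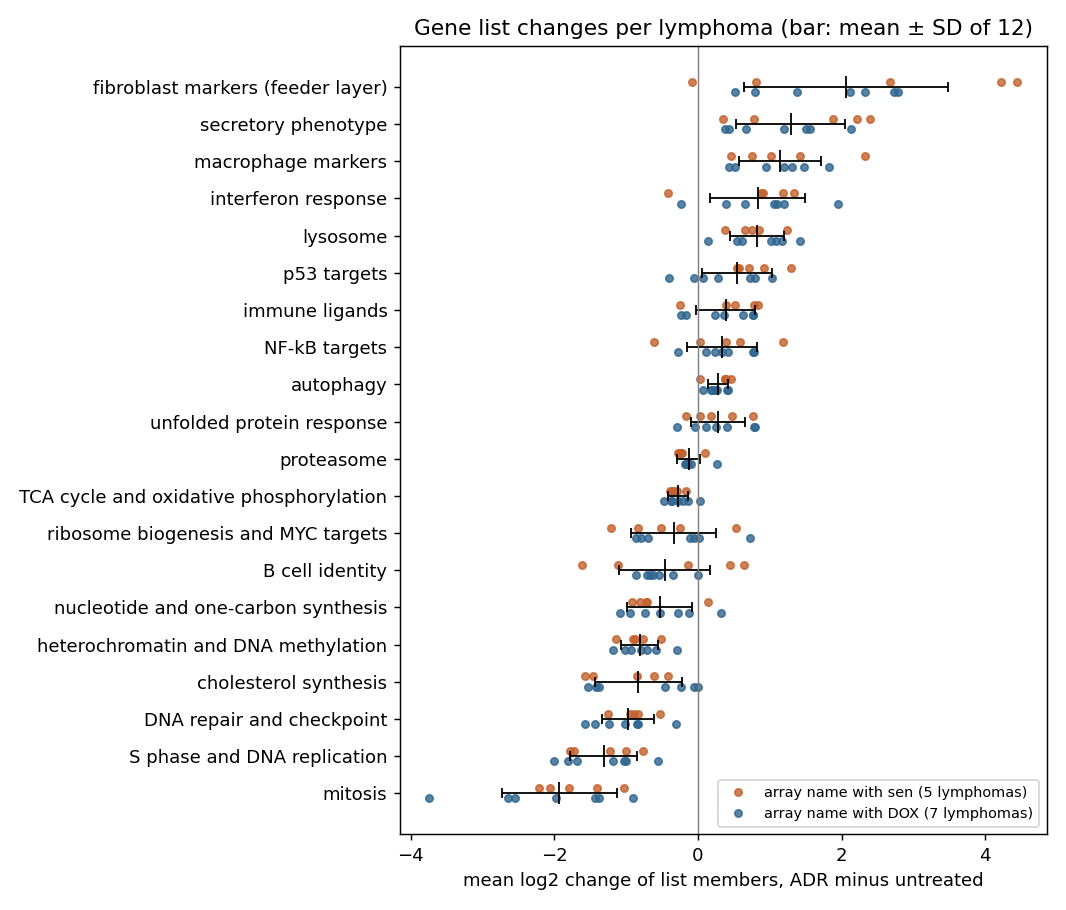
Mean log2 change of the measured members of the 20 called lists (horizontal axis, ADR minus untreated), with 1 point per lymphoma and black bars for the mean ± SD of 12; orange points are lymphomas with sen and blue with DOX in the treated array's name. The mitosis list lies between -3.74 and -0.91 and the fibroblast marker list between -0.09 and 4.45.

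In all, camera called 10 lists higher and 10 lower of 32, and 0 with an estimated correlation, where 9 had an unadjusted p under 0.05. The rotation test fry called 13 higher and 8 lower, and the exact sign-flip permutation test called 23.

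The naming sets gave the same direction for the leading groups. Mitosis genes changed by -1.70 ± 0.49 (SD, n = 5) in the sen set and by -2.09 ± 0.96 (SD, n = 7) in the DOX set, and secretory phenotype genes by 1.53 ± 0.91 and 1.12 ± 0.66. In the sen set alone 811 genes were called and in the DOX set alone 3250. By limma's interaction test 0 genes differed between the sets in their change, with 1237 at an unadjusted p under 0.05, where 910 are the chance number.

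The 3' over 5' difference of the Gapdh control probe sets, a sign of RNA integrity, was 0.01 ± 0.04 in untreated and 0.13 ± 0.29 in ADR arrays (SD, n = 12, exact sign-flip permutation p = 0.247). The ADR arrays of lymphomas 1570 and 6054 stood apart at 0.945 and 0.401. For Actb the values were 0.39 ± 0.22 and 0.38 ± 0.26 (p = 0.899, the same permutation test). Without these lymphomas 4196 genes were called, and without 5560 and 403, where fibroblast markers changed most, 3894.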

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

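The interaction of treatment with the naming sets, the fits within each set and the fit with macrophage and fibroblast markers as covariates were planned; their use to weigh explanations, and the other tests in this part, were chosen after the results were seen.

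The first pattern is the rise of the secretory phenotype list. A candidate explanation is RNA of the feeder fibroblasts, of whose 29 markers 25 rose. Where the fibroblast markers do not change, the fitted secretory phenotype change was 0.25 (95% interval -0.05 to 0.55), against 1.29 as measured. Feeder RNA predicts this, but list members that fibroblasts also express would follow the markers whatever the lymphoma cells did. No step to remove feeder cells is given in the labels. The same fit on macrophage markers gave 0.98 (interval -0.18 to 2.14) with a slope whose interval holds 0, so RNA of macrophages cannot be told apart by it, and secretion by the lymphoma cells themselves, or a stronger treatment effect on both lists, remains open.

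The second pattern is the fall of the mitosis list. If feeder RNA had only diluted lymphoma RNA, mitosis genes would have fallen no further than B cell identity genes, yet the difference was -1.47 ± 1.14 (SD, n = 12), below 0 in 11 of 12 lymphomas, all but 5560 (exact sign-flip permutation p = 0.00195). This takes B cell identity genes as a gauge of lymphoma RNA. Transcripts of these genes from other cells would hold that list up, which was not tested. The smaller fall of the naming sets was -1.70, in the sen set, so the fall was not limited to 1 set. Pairs were compared within a set, so a difference in level between the sets could not have made it. A difference in processing between treated and untreated arrays was not tested. With macrophage and fibroblast markers as covariates the mean change was -2.38 against -1.93, but the median standard error of its genes went from 0.23 to 0.59 and 0 of 35 genes were called. A fall of these genes with ADR is the hypothesis that remains among those tested.

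The third pattern is the rise of the lysosome list. Where fibroblast markers do not change the fitted change was 0.49 (95% interval 0.12 to 0.86), so feeder RNA alone falls short. RNA of macrophages is a candidate explanation: the fitted change where macrophage markers do not change was 0.35 (interval -0.12 to 0.81), and 0.014 (interval -0.36 to 0.39) where neither marker list changes. Macrophage markers rose in all 12 lymphomas, by 0.43 to 2.32. Both fitted values are thus extrapolated beyond the data and cannot decide the question. A rise within treated lymphoma cells was not separated from RNA of macrophages by any value here.

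Other splits of the samples, made by swapping the labels within some pairs, gave fewer genes. The real labels gave 4829 changed genes and 1 of 100 splits, the real one, reached that number; the highest other was 4151. For genes changed at least 2-fold the real count was 1012, again 1 of 100, with 841 as the highest other. The splits nearest to the real one swapped 1 pair. Chance is thus an unlikely source of both counts, though 100 splits cannot exclude it. The number of lists called by camera did not stand out: the real labels gave 20, and 15 of 100 splits gave as many. The highest other was 23 and the median of the others 11, so chance remains possible there. For genes whose change differs between the naming sets the count was 0, which every split reaches (100 of 100, with 5 as the highest other), so splits decide nothing there.

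By camera's interaction test, 5 lists differed in their change between the naming sets. The change in the DOX set minus that in the sen set was -0.39 for mitosis (adjusted p = 0.00843), -0.46 for p53 targets (0.000423), 0.20 for ribosome biogenesis and MYC targets (0.0429), 0.26 for cholesterol synthesis (0.0429) and -0.60 for fibroblast markers (0.0429). In an exact permutation test over all 792 splits of the 12 lymphomas, each of the 5 had an adjusted p of 0.998. Among 10092 probe sets with no gene symbol or several, which the comparisons did not use, 856 changed (340 higher and 516 lower by limma).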

How the results depend on the processing

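The settings with fibroblast markers alone, and without lymphomas 1570 and 6054 or 5560 and 403, were chosen after seeing the data. The 2 marker covariates move with treatment, so these fits have less power. Macrophage markers rose in all 12 lymphomas, by 0.43 to 2.32, so estimates with both markers are extrapolated beyond the data. The cause of the other shifts was not tested. Weak signal near the array floor limits small changes.

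Genes changed numbered 3210 without the replicate block (1630 higher), 811 in the sen set (338 higher, 473 lower), 2840 at an adjusted p under 0.01, and 8880 when all probe sets were counted. In the DOX set 1649 were higher. With fibroblast markers as a covariate the numbers were 1071 (446 higher, 625 lower), 431 at least 2-fold (121 higher) and 6 lists higher. With macrophage markers too, 0 genes changed, 0 were higher, 0 lower, 0 changed at least 2-fold, 0 were higher and 0 lower by that much, and 2 lists were higher. At least 2-fold, the sen set had 436 (183 higher), and limma's treat, which tests against a 2-fold change itself, 23. With an estimated correlation 0 lists were higher and 0 lower.

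Leaving out 1 lymphoma gave 3966 to 5165 genes changed (2038 to 2624 higher, 1928 to 2541 lower), 871 to 1113 at least 2-fold (552 to 728 higher, 319 to 398 lower), and 9 to 11 lists higher and 10 to 11 lower. The block changed the call of 1 list (immune ligands) and 30 of 124 named genes.

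Among called lists, signs turned with fibroblast markers as a covariate for NF-kB targets (-0.057), immune ligands (-0.012), B cell identity (0.31), ribosome biogenesis and MYC targets (0.39) and proteasome (0.0033). Genes that turned were Ereg (-0.45), Nectin2 (-0.39), Pvr (-0.032), Fcrla (0.31), Myb (0.64), Bach2 (0.78), Igll1 (0.20), Sdc1 (-0.12), Nop58 (0.29), Gar1 (0.24), Wdr12 (0.24), Eno2 (-0.70), Map1lc3a (-0.14), Ddit3 (-0.30), Bcl2l2 (-0.15), Cd34 (-0.17), Mecom (-0.49), Sox9 (-0.21), Lgr5 (0.34) and Myc (0.31). None of these genes was called in that fit, so none was shown to go the other way.

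With both markers, signs turned among called lists for p53 targets (-0.062), secretory phenotype (-0.062), NF-kB targets (-0.61), interferon response (-0.11), immune ligands (-0.42), ribosome biogenesis and MYC targets (0.52), nucleotide and one-carbon synthesis (0.20) and proteasome (0.086). Genes that turned were Cxcl5 (-0.86), Vasn (-0.33), Phlda3 (-0.26), Eda2r (-0.036), Ereg (-1.45), Tnfaip2 (-0.26), Cd83 (-1.11), Oasl2 (-0.22), H2-D1 (-0.49), Ctss (-0.34), Cd274 (-0.81), Nectin2 (-0.58), Pvr (-0.16), Myb (0.20), Bach2 (0.86), Sdc1 (-0.84), Nop58 (0.29), Gar1 (0.27), Wdr12 (0.35), Shmt2 (0.080), Slc16a1 (0.079), Eno2 (-0.51), Idh3a (0.032), Ctsl (-0.44), Map1lc3a (-0.021), Gabarap (-0.17), Atf3 (-0.38), Ddit3 (-0.46), Mcl1 (-0.12), Cd34 (-0.20), Procr (-0.17), Sox9 (-0.34), Jun (-0.41), Fcgr1 (-0.085), Fn1 (-0.43), Myc (0.017), Glb1 (-0.21) and Il6 (-0.24). None of these genes was called in the fit with both markers. Fcgr1 and Fn1 belong to the lists whose means were the covariates, so each was in part adjusted for itself. The probe set with the largest variance turned Syk (-0.20), Psma1 (0.064) and Bcl2 (0.092), none of them called.

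Of the counts under other settings 100 stayed within 1.5 times and 26 did not, and all 96 did with 1 lymphoma left out. For called named genes under other settings 1265 values kept call and direction, 332 lost the call and 61 turned; with 1 lymphoma left out 1360 kept and 68 lost it. Lists and genes without a call are not in these counts; among them B cell progenitor (0.36 and 0.41) and haematopoietic stem cell (-0.039 and -0.0017) turned with fibroblast markers and with both, and plasma cell (-0.25), MHC class I presentation (-0.084) and BCL2 family (-0.015) with both. NF-kB targets lost their call without 2581, and immune ligands without 3594, 3769 or 7050. With 1 lymphoma left out 6 list calls were gained: glycolysis without 3594 or 5560, and neutrophil markers without 1570, 3802, 5766 or 7050. Under other settings 16 were gained, among them neutrophil markers with fry (adjusted p = 0.00114) and without 1570 and 6054 (0.031), and MHC class II presentation with both markers (-0.79, adjusted p = 0.000438), and 41 were lost. Of the signs turned with both markers, those of NF-kB targets (adjusted p = 0.00024), immune ligands (0.0129) and ribosome biogenesis and MYC targets (3.0e-08) passed camera. A marker list has no value of its own where it is the covariate.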

Other observations

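The Eif2s3y test in this part was chosen after the result was seen. Lymphomas differed in which gene groups moved. In lymphoma 2949 the mitosis list had its largest fall (-3.74), while its p53 target and interferon response changes were -0.40 and -0.24 and its ribosome biogenesis and MYC target change 0.73. In lymphoma 1467, where fibroblast markers changed by -0.09, mitosis genes changed by -1.79, macrophage markers by 1.42, interferon response genes by 0.91 and secretory phenotype genes by 0.35. Its treated sample is labelled yes for senescence induction where the other 11 are labelled TIS, and in deviation from the group mean its treated array correlated less with its own untreated array (0.349) than with that of another lymphoma (0.509), as was also the case for 5766 (0.589 and 0.66). Cholesterol synthesis changed by -1.57 in 2581, -1.53 in 7050 and -1.46 in 1570, against -0.06 in 3594 and 0.00 in 3802.

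Sex-linked transcripts, read to check that arrays of a pair match, gave high or low Xist alike in both arrays of all 12 lymphomas. Xist could not show a swap between lymphomas alike in its level, and 1467 and 5766 both had high Xist. The Y-linked genes mostly rose together, though many values lay near the floor. Kdm5d was lower after ADR only in 7050, Uty only in 7050 and 2949, and Eif2s3y only in 403. In 5560 Kdm5d went from 2.55 to 3.35 and Uty from 2.94 to 3.27. In 7050, with high Xist, Kdm5d went from 5.02 to 3.89 and Uty from 3.59 to 3.16 while Eif2s3y went from 2.62 to 3.65. Untreated 3802, with low Xist, had Kdm5d at 6.35 and Eif2s3y at 2.79. The Y-linked gene Eif2s3y was between 2.49 and 2.94 in 10 untreated arrays and was higher after ADR in all 10 of these lymphomas, by 0.72 ± 0.58 (SD, n = 10). The largest change was 1.84, in lymphoma 5560 (2.67 to 4.51), and lymphoma 3769 went from 2.65 to 4.21. A hypothesis is that this RNA came from feeder fibroblasts and not from the lymphomas. The change followed the fibroblast marker change (Pearson r = 0.813, permutation p = 0.00291, Spearman rho = 0.673, p = 0.0391). Without lymphomas 1467 and 5560 r was 0.555 over 8 (exact permutation p = 0.158), so the relation rests on them. Kdm5d and Uty rose in most lymphomas. Their values in 7050 go against reading Y-linked transcripts as feeder RNA alone, and the hypothesis stays open.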
